A study of Pseudomonas chlororaphis subsp. aureofaciens 30-84 with 4 samples.

How the data were processed

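RNA was measured by RNA sequencing in 4 libraries of Pseudomonas chlororaphis strain 30-84, a soil and root bacterium: 2 of the wild type and 2 of a phenazine-deficient derivative named ZN. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, each library came from its own broth culture, started from a single colony on separate plates, in AB minimal medium with 2% casamino acids at 28 °C, shaken at 200 rpm in 10 ml and harvested at an optical density of about 2.0. RNA was treated with DNase on the column, 300 ng of rRNA-depleted RNA was fragmented at 95 °C for 5 min, and strand-specific libraries were made with a SOLiD kit, with amplicons of 200 to 300 bp selected.

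The authors deposited 1 table of RPKM values (reads per kilobase of gene, scaled to the reads of the library), per the file headers, with 1 column for each library and a locus tag, a gene name and a product for each gene. RPKM values are not counts, so a count test was not the main test. The aligner, the read counter and the genome build are not given in the sources used here, and no coordinates are printed. The table held 6029 rows, of which 69 named no locus, and 14 of the 5960 loci had no value. Of the 5946 loci with values, 39 were listed at 0 in every library. They included rpoN and csrA, regulators that cells of this genus use, so a 0 is taken only as listed at 0.

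Gene lengths came from the RefSeq annotation of assembly ASM28191v1, matched by older locus tags, for 5847 loci (98.3%). Symbols and products were those of the table. Multiplied by gene length less 1 base, the RPKM values of most genes were whole multiples of a fixed step in each library. That step gave 30230000 and 28990000 reads behind the values of wild-type replicates 1 and 2, and 25060000 and 33340000 behind those of mutant replicates 1 and 2. Between 82.3% and 82.7% of the values of genes with a length came out whole within 0.05 reads, and 4671 genes did so in all 4 libraries. The median gene had 391 to 502 reads in a library. Tested on 8 simulated libraries of 5847 genes, of which 4 had 20% of their lengths changed, the search found the step with an error of at most 0.0%.

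The comparison used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) for genes with a mean RPKM of at least 1 over the 4 libraries, which left 5905 genes. The moderated test (lmFit and eBayes with a mean-variance trend) was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are differences of mean log2(RPKM + 1), mutant minus wild type, which understates the change of genes with low values. The replicate number was not used as a block. Errors are SD over n = 2 libraries.

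Gene lists were 26 sets fixed by symbol and product name before the data were examined. The 25 with at least 3 members tested entered camera, with its preset inter-gene correlation of 0.01, and p-values were adjusted over lists. Type III secretion, with fewer members, was not tested. camera compares a list with all other genes. The same test with a correlation estimated from the 4 libraries was run beside it, and so was fry, which tests whether a list moves on balance in 1 direction. None of the 12 lists called with the preset correlation was called by either. Both rest on the 2 residual degrees of freedom left by 4 libraries, so a call after adjustment over 25 lists was hardly possible. Terminal oxidases had an estimated correlation of 0.01, the preset value, and their camera adjusted p still went from 0.035 to 0.61. A list not called there is therefore not argued against. The estimate was 0.83 for ribosomal proteins, 0.75 for phenazine biosynthesis, 0.54 for phage and bacteriocins, 0.49 for siderophores and 0.40 for type VI secretion. It was 0.33 for rRNA and tRNA genes, 0.32 for ATP synthase and TCA cycle and 0.17 for oxidative stress defence. In all of these the preset may call too readily. For the other called lists the estimate ran from -0.11 (quorum sensing) to 0.08 (other secondary metabolites). Because the median log2 fold change of all genes was 0.19, the change of a list is also given as its median less that of all genes, called its relative median. For each list, genes were also counted after adjustment over the list alone. Runs of at least 3 neighbouring called genes were compared with 1000 random orders of the genes.

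Named genes followed a rule fixed before the data were examined: every measured gene of the phenazine list with phzI and phzR; the 12 genes with the largest positive and the 12 with the largest negative change past the threshold, in the same direction in all 4 pairs of a mutant and a wild-type library; the 2 largest in each direction among such genes with no known product; and up to 4 genes past the threshold from each list that was called or had at least 3 such genes. As no gene passed the threshold, only the first part named any. Every other gene named was chosen after its values were seen.

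On simulated values of 5905 genes with the spread of these libraries, the fit of mutant against wild type recovered 90.4% of genes changed 4-fold and 25% of those changed 2-fold, with 6.6 false calls on average over 5 simulations. The noise was drawn for each gene independently, and 200 changed genes were planted, none of them at low levels. Recovery in the real libraries may be lower: phzB was 5.39 times lower in the mutant at a limma adjusted p of 0.12. Missed 4-fold changes are therefore not excluded. Alternatives fixed before the data were examined were 2 other pseudocounts, 2 other filters, 2 other scalings, 2 other variance models, the replicate number as a block, leaving out each library, other thresholds and other set tests. Subtraction of each library's 1st percentile, rescaling without the 3 most abundant small RNAs, and limma's voom on the recovered whole reads were chosen after seeing the data. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.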

Results

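Transcript levels were compared between wild-type Pseudomonas chlororaphis 30-84 and its ZN mutant, which the labels describe as deficient in phenazines, the redox-active pigments and antibiotics of this bacterium. The series asks which genes depend on phenazines. Each strain was represented by 2 libraries from separate cultures, with 30230000 and 28990000 reads behind the values of wild-type replicates 1 and 2 and 25060000 and 33340000 behind those of mutant replicates 1 and 2. Reads in genes with a length came to 14010000, 13180000, 11600000 and 15390000. Of these, tmRNA took 19.7% to 24.7%, and RNase P RNA took 9.2% and 7.7% in the wild type and 12.9% and 12.3% in the mutant.

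The wild-type libraries had a Pearson correlation of 0.979 across genes on the log2 scale, and the mutant libraries of 0.941. Between strains it ran from 0.946 to 0.977, with the highest value between mutant replicate 2 and wild-type replicate 2. These are correlations across genes, which are not independent replicates. Mutant replicate 1 had few low values: the 1st percentile of its values above 0 was 6.12 RPKM, against 2.02 and 1.81 in the wild type and 2.11 in mutant replicate 2.

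**Figure D1:**
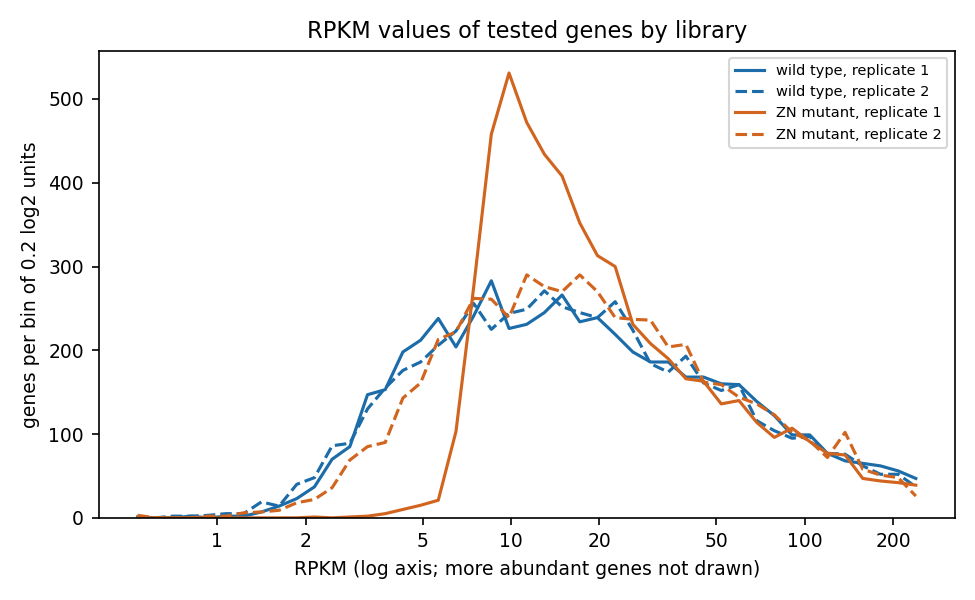
Number of tested genes (y axis, per bin of 0.2 log2 units) by RPKM (x axis, log scale, more abundant genes not drawn) in each library, with solid lines for replicate 1 and dashed lines for replicate 2. Few genes of mutant replicate 1 lie under its 1st percentile of 6.12 RPKM, where the other 3 libraries have many.

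In the ZN mutant the transcripts of the phenazine operon were 3.40 to 5.39 times lower than in the wild type, as ratios of mean RPKM. In earlier work on this strain ZN carries a lacZ insertion in phzB, and RPKM counts reads along the whole gene, upstream of an insertion included. For phzB (Pchl3084_4952) the RPKM was 75.3 and 33.6 in the wild type and 15.2 and 5.01 in the mutant, or 54.5 ± 29.5 against 10.1 ± 7.20 (SD, n = 2 libraries), from 1118, 478, 187 and 82 recovered reads. Its log2 fold change was -2.38 ± 0.46 (SE, limma adjusted p = 0.12), with lower values in 4 of 4 pairs of libraries. The log2 fold change was -2.13 for phzA, -1.95 for phzC, -1.66 for phzD, -1.83 for phzE, -2.16 for phzF and -2.04 for phzG, the other genes of the core pathway. With 1 library left out it ran from -2.90 to -1.36 for phzA and from -3.10 to -1.67 for phzB, lowest without mutant replicate 1 and highest without mutant replicate 2. For phzD it was -1.07 without wild-type replicate 1. For phzO, whose product hydroxylates phenazine-1-carboxylic acid, it was -1.75 ± 0.32, with 53.3 ± 21.3 RPKM in the wild type and 15.0 ± 5.27 in the mutant (SD, n = 2). Both members outside the operon, which encode proteins of the PhzF family, had other values: 0.28 for Pchl3084_2139 and -0.09 for Pchl3084_4663. The sign of Pchl3084_2139 turned with quantile normalization (-0.33) and without mutant replicate 1 (-0.12).

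Of the 10 genes of the phenazine list, 0 passed the threshold over all genes tested and 8 did so, all lower, when adjusted over the list alone (phzA to phzG and phzO, adjusted p from 0.00091 to 0.0027). The mutant is labelled phenazine deficient, so these genes served as a check of the labels. They are neighbours in an operon, and the list had an estimated correlation of 0.75, so they do not count as 8 independent genes. The list fell, with a median log2 fold change of -1.89 and a relative median of -2.08 (camera adjusted p = 1.1e-10, and adjusted p = 0.61 with an estimated correlation). With 1 library left out, the median of the list ran from -2.42 without wild-type replicate 2 to -1.39 without wild-type replicate 1. phzI and phzR, the synthase and the regulator of the quorum-sensing system next to the operon, had log2 fold changes of -0.69 ± 0.32 and -0.86 ± 0.39 (SE, limma adjusted p = 0.48 for both), with lower values in 3 of 4 pairs. With 1 library left out, phzI was at -0.24 without wild-type replicate 1 (adjusted p = 0.97), -1.14 without wild-type replicate 2 (0.12), -0.95 without mutant replicate 1 (0.11) and -0.44 without mutant replicate 2 (0.34), with 0.027 to 0.97 over the alternatives. phzR passed the threshold without wild-type replicate 2 (-1.31, limma adjusted p = 0.021) and without mutant replicate 1 (-1.43, adjusted p = 0.0085). It was at -0.40 without wild-type replicate 1 (adjusted p = 0.97) and -0.29 without mutant replicate 2 (adjusted p = 0.58), with 0.0032 to 0.97 over the alternatives.

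**Figure D2:**
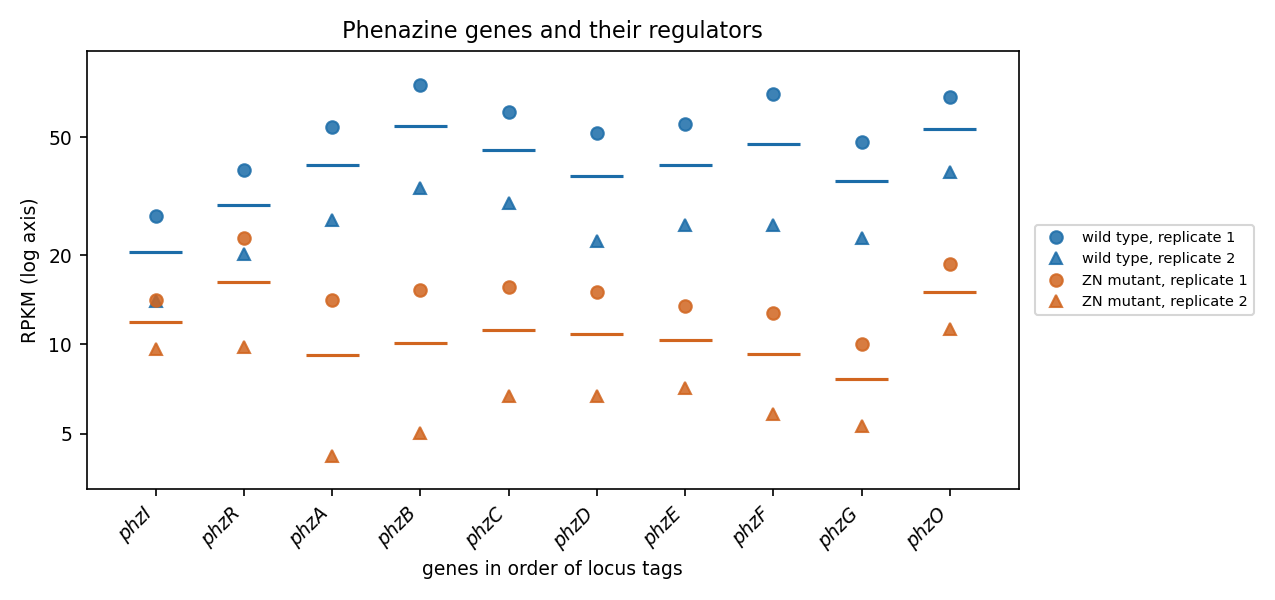
RPKM (y axis, log scale) of phzI, phzR and the phenazine operon (x axis), in the order of their locus tags, in each of the 4 libraries. Points are libraries, short lines are the mean of each strain, and for phzA to phzO all mutant values lie below all wild-type values.

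Across all genes, 0 of 5905 passed an adjusted p of 0.05 in limma, and 604 had an unadjusted p under 0.05 (332 higher and 272 lower in the mutant). voom on recovered reads also called 0 of 4671 genes, with 525 under an unadjusted p of 0.05. The median log2 fold change of all genes was 0.19, against 0.02 with quantile normalization and 0.04 with median of ratios scaling, and those scalings gave 148 higher and 245 lower, and 141 higher and 455 lower, at an unadjusted p under 0.05. Of scalings chosen after seeing the data, background subtraction gave 99 higher and 283 lower, and rescaling without the 3 most abundant small RNAs 655 higher and 169 lower. All 4 pairs agreed in direction for 2072 higher genes (35.1%) and 910 lower genes (15.4%), where chance gives 16.7% each way if no library is shifted as a whole. The pairs used RPKM as deposited, with no rescaling. The excess of higher genes may therefore come from scale or from the raised low values of mutant replicate 1, and is not read as an effect of the strain. The count of 0 rose to 1271 without mutant replicate 2, 107 without mutant replicate 1, 129 without wild-type replicate 2 and 35 without wild-type replicate 1, where the lone library of a strain is assumed to vary like the other strain's.

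The histidine utilization genes were the lowest in adjusted p. In this cluster hutU (Pchl3084_0401), the gene of urocanate hydratase, had 455.0 ± 38.1 RPKM in the wild type and 130.2 ± 23.6 in the mutant (SD, n = 2), a log2 fold change of -1.81 ± 0.26 (SE, limma adjusted p = 0.063). Of the neighbouring hutH genes, Pchl3084_0407, which encodes histidine ammonia-lyase, had 98.4 ± 0.97 against 28.1 ± 2.77 RPKM and a log2 fold change of -1.77. The log2 fold change was -1.39 for the hutH gene Pchl3084_0406, -1.39 for hutI and -1.47 for hutG. The transport genes between them gave -1.62 for the permease Pchl3084_0402, -1.67 for hisX, -1.28 for hisV, -1.11 for hisW and -0.99 for proY. All of these were lower in 4 of 4 pairs. They were chosen after their values were seen, and 6 of them had a limma adjusted p under 0.1 (0.063 to 0.093). With 1 library left out, the log2 fold change of hutU ran from -1.99 without mutant replicate 2 to -1.62 without mutant replicate 1. Such a fit takes its spread from the pair of 1 strain alone, so passing the threshold in it is not read as support. With the robust variance model, hutU, Pchl3084_0402, hisX, hisV, both hutH genes, hutI and hutG passed the threshold. For hutU the limma adjusted p was 0.0039 there. Over the other fits of all 4 libraries it ran from 2.8e-06 (replicate block, which leaves fewer residual degrees of freedom) to 0.64 (background subtraction). In the list of arginine deiminase and amino acid catabolism, which camera placed below the other genes (18 genes, 9 positive and 9 negative, camera adjusted p = 0.00028, and adjusted p = 0.61 with an estimated correlation), 4 members passed when adjusted over the list alone: hutU, both hutH genes and hutI. The list's median was 0.01 and its mean -0.35, so that the median and the test differ in sign. The relative median was -0.18, and -0.41 without wild-type replicate 1 and -0.37 without mutant replicate 2.

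**Figure D3:**
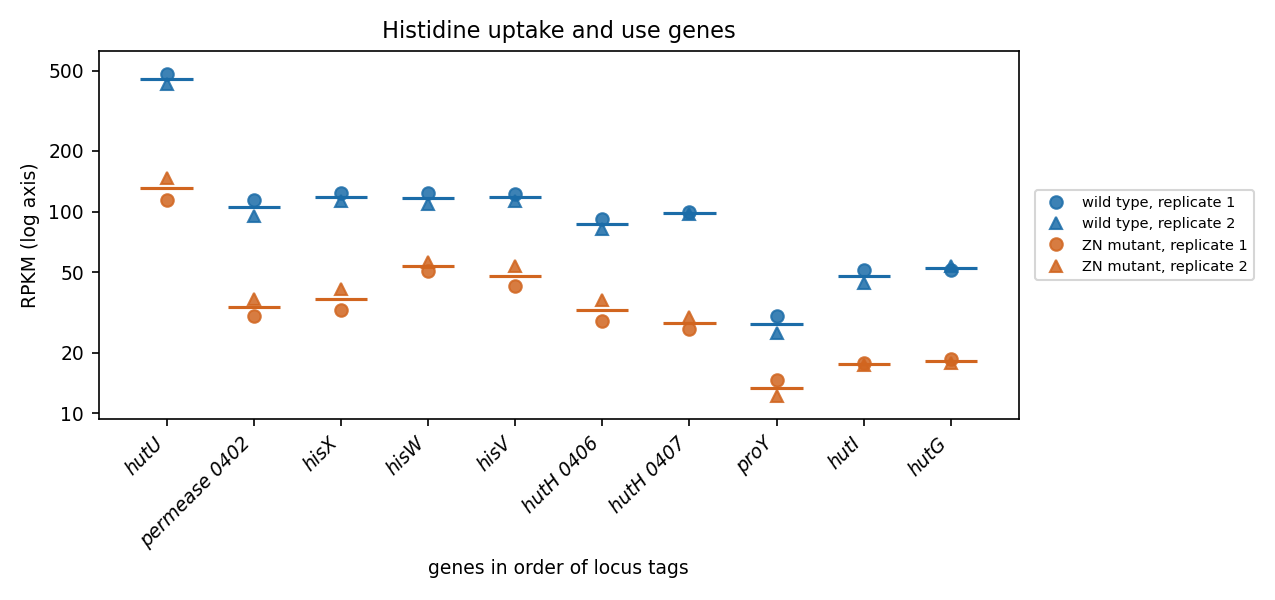
RPKM (y axis, log scale) of 10 neighbouring genes of histidine uptake and use (x axis), in the order of their locus tags, in each of the 4 libraries. Points are libraries, short lines are the mean of each strain, and all mutant values lie below all wild-type values.

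The 4 genes of pyrrolnitrin synthesis, an antifungal antibiotic, had log2 fold changes of -0.99 (prnA), -0.90 (prnB), -1.29 (prnC) and -1.10 (prnD), and prnA had 976 ± 200.0 RPKM in the wild type and 491 ± 91.4 in the mutant (SD, n = 2). They were the 4 of 17 members of the list of other secondary metabolites that passed when adjusted over the list alone (adjusted p from 0.021 to 0.047). Over all genes the limma adjusted p of these 4 neighbouring genes was 0.24 to 0.44. camera placed that list below the other genes (8 members positive and 9 negative, relative median -0.35, camera adjusted p = 0.031, and adjusted p = 0.61 with an estimated correlation). It was not called without wild-type replicate 1 (-0.16, adjusted p = 0.12) or mutant replicate 1 (-0.07, adjusted p = 0.17), was -0.74 without mutant replicate 2, and had an adjusted p from 0.002 to 0.68 over the alternatives. The hydrogen cyanide genes hcnA, hcnB and hcnC had log2 fold changes of -0.68, -0.74 and -0.85, with hcnA at 240 and 202 RPKM in the wild type, 89.1 in mutant replicate 1 and 211 in mutant replicate 2. Of 29 secreted hydrolase genes, 3 were lower when adjusted over the list alone (adjusted p = 0.0039 each): the chitinase gene chiC (Pchl3084_2021, 8255 ± 1734 against 2885 ± 1021 RPKM), its neighbour Pchl3084_2020 for a chitin-binding protein (-1.34), and the alkaline protease gene aprA (1431 ± 460 against 499 ± 57.6 RPKM, SD, n = 2). Over all genes their limma adjusted p was 0.12, 0.13 and 0.12. The list as a whole was not called (relative median 0.05, camera adjusted p = 0.71). camera placed the quorum sensing list below the other genes (8 genes, relative median -0.54, camera adjusted p = 0.035, and adjusted p = 0.61 with an estimated correlation), with 6 members negative and 0 past the threshold in limma. It was not called without wild-type replicate 1 (adjusted p = 0.09) or mutant replicate 2 (adjusted p = 0.13), with adjusted p from 0.015 to 0.61 over the alternatives. Another synthase and regulator pair, csaI and csaR, had log2 fold changes of -0.42 and -0.41.

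camera placed the 45 genes of oxidative stress defence below the other genes (19 positive and 26 negative, relative median -0.23, camera adjusted p = 0.0083, and adjusted p = 0.76 with an estimated correlation). It was not called without wild-type replicate 1 (-0.15, adjusted p = 0.09) or mutant replicate 2 (-0.28, adjusted p = 0.13), and was -0.36 without wild-type replicate 2, with adjusted p from 0.00094 to 0.76 over the alternatives. Adjusted over the list alone, 2 members passed. sodB, a superoxide dismutase gene, had 231 ± 3.64 RPKM in the wild type and 91.1 ± 10.3 in the mutant (log2 fold change -1.33). katA, a catalase gene, had 86.1 ± 2.22 and 43.7 ± 1.18 (SD, n = 2 for both genes). Their limma adjusted p was 0.011 and 0.044 over the list alone, and 0.12 and 0.28 over all genes. Among 24 genes of iron storage, iron-sulfur clusters and Fur, bfr (Pchl3084_5292), the bacterioferritin gene beside katA, was higher when adjusted over the list alone (limma adjusted p = 0.046, and 0.28 over all genes). It had 263 ± 48.0 RPKM in the wild type and 647 ± 239 in the mutant (SD, n = 2), with 816 in mutant replicate 1 and 478 in mutant replicate 2. Its log2 fold change was 1.26, and 0.87 without mutant replicate 1. The list of iron storage, iron-sulfur clusters and Fur was not called (relative median -0.07, camera adjusted p = 0.49).

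camera placed the siderophore and iron uptake list above the other genes (61 genes, 59 of them positive, relative median 0.46, camera adjusted p = 1.1e-07, and adjusted p = 0.76 with an estimated correlation). Adjusted over the list alone, 0 members passed. Its median gene had 4.32 and 4.16 RPKM in the wild type, 9.09 in mutant replicate 1 and 5.88 in mutant replicate 2, where the 1st percentile of mutant replicate 1 was 6.12 RPKM. The relative median was 0.11 with quantile normalization, 0.21 without mutant replicate 1 and 0.74 without mutant replicate 2, and the list was not called among genes with a mean RPKM of at least 10 (0.19, adjusted p = 0.6, with 3.6e-10 to 0.76 over the alternatives). camera also placed the phage and bacteriocin list above the other genes (35 genes, relative median 0.34, camera adjusted p = 0.021, and adjusted p = 0.78 with an estimated correlation). Adjusted over the list alone, 0 members passed. Its median gene had 14.0 and 16.3 RPKM in the wild type, 31.0 in mutant replicate 1 and 15.45 in mutant replicate 2. Its relative median was -0.12 without mutant replicate 1 (adjusted p = 0.6), 0.24 without wild-type replicate 1 (adjusted p = 0.16) and 0.80 without mutant replicate 2, with adjusted p from 7.4e-07 to 0.78 over the alternatives.

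camera placed ribosomal protein genes below the other genes (52 genes, 50 of them negative, median log2 fold change -0.63, relative median -0.81, camera adjusted p = 2.5e-20, and adjusted p = 0.61 with an estimated correlation and 0.64 with fry). Adjusted over the list alone, 0 members passed. Their median gene had 203 and 199 RPKM in the wild type, 91.0 in mutant replicate 1 and 177 in mutant replicate 2, so that the relative median was -0.31 without mutant replicate 1 and -1.28 without mutant replicate 2. camera placed ATP synthase and TCA cycle genes below the other genes (24 genes, 4 positive and 20 negative, relative median -0.59, camera adjusted p = 1.3e-08, and adjusted p = 0.61 with an estimated correlation and 0.46 with fry). Their median gene had 88.15 and 77.55 RPKM in the wild type, 51.15 in mutant replicate 1 and 71.2 in mutant replicate 2, and the relative median was -0.35 with quantile normalization. The 1 member that passed when adjusted over the list alone was prpC (limma adjusted p = 0.013, and 0.15 over all genes), which encodes 2-methylcitrate synthase, an enzyme of propionate use and not of the TCA cycle. camera placed type VI secretion genes below the other genes (40 genes, 13 positive and 27 negative, relative median -0.26, camera adjusted p = 0.00092, and adjusted p = 0.76 with an estimated correlation). They were not called without wild-type replicate 1 (-0.05, adjusted p = 0.12), and the value was -0.45 without wild-type replicate 2, with adjusted p from 7.4e-06 to 0.76 over the alternatives. camera also placed below the other genes the rRNA and tRNA genes (69 genes, 36 positive and 33 negative, relative median -0.17, camera adjusted p = 0.028, and adjusted p = 0.78 with an estimated correlation) and the terminal oxidases and anaerobic respiration genes (41 genes, 20 positive and 21 negative, relative median -0.25, camera adjusted p = 0.035, and adjusted p = 0.61 with an estimated correlation). Neither was called with quantile normalization (adjusted p = 0.81 for both, with 7.4e-06 to 0.97 and 0.029 to 0.81 over the alternatives). The rRNA and tRNA genes were not called without wild-type replicate 1 (0.01, adjusted p = 0.48) or mutant replicate 2 (-0.27, adjusted p = 0.36), and were at -0.44 without wild-type replicate 2. The oxidases were not called without wild-type replicate 1 (-0.16, adjusted p = 0.075), wild-type replicate 2 (-0.42, adjusted p = 0.16), mutant replicate 1 (-0.10, adjusted p = 0.17) or mutant replicate 2 (-0.32, adjusted p = 0.11). The rRNA and tRNA list had a median of 0.01 and a mean of 0.05, and the oxidase list a median of -0.06 and a mean of 0.02, so that the test differs in sign from both values of the rRNA and tRNA list and from the mean of the oxidase list.

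**Figure D4:**
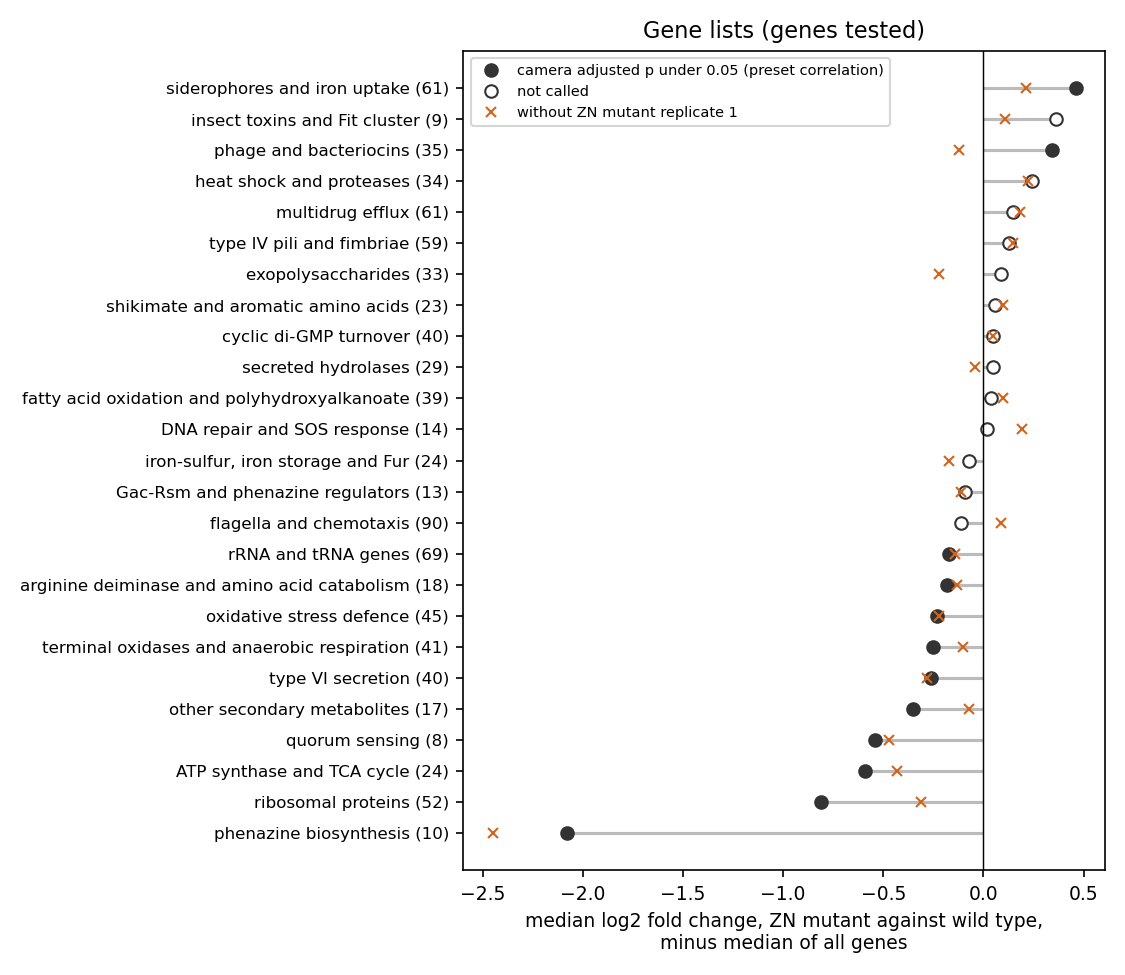
Median log2 fold change of each gene list less the median of all genes (x axis), for each list on the y axis, with the number of genes tested in brackets. Filled circles are lists with a camera adjusted p under 0.05 at the preset correlation, open circles the others, and crosses the value without mutant replicate 1, which for phage and bacteriocins is -0.12 against 0.34 with all libraries.

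The other lists were not called by camera. Relative medians were 0.15 for multidrug efflux (adjusted p = 0.072), 0.13 for type IV pili and fimbriae (0.13), -0.11 for flagella and chemotaxis (0.16), 0.36 for insect toxins and the Fit cluster (0.3), -0.09 for Gac-Rsm and phenazine regulators (0.43), 0.24 for heat shock and proteases (0.49) and 0.06 for shikimate and aromatic amino acids (0.49). They were 0.02 for DNA repair and SOS response, 0.09 for exopolysaccharides and 0.04 for fatty acid oxidation and polyhydroxyalkanoate (adjusted p = 0.71 each), and 0.05 for cyclic di-GMP turnover (0.75). The test pointed down while median and mean lay above 0 for flagella, Gac-Rsm, shikimate, exopolysaccharides and fatty acids, and also for secreted hydrolases and iron storage. With quantile normalization the relative median was -0.12 for exopolysaccharides and 0.00 for fatty acids and secreted hydrolases. Some were called with another scaling or filter, on recovered reads or with 1 library left out. Multidrug efflux was called with median of ratios scaling (0.15, adjusted p = 0.045), without wild-type replicate 2 (0.23, 0.039) and without mutant replicate 1 (0.18, 0.014). It was at 0.06 with quantile normalization and 0.01 with background subtraction, with adjusted p from 0.014 to 0.91 over the alternatives. Flagella and chemotaxis was called with quantile normalization (-0.10, adjusted p = 0.035), without wild-type replicate 1 (-0.22, 0.0024) and without mutant replicate 2 (-0.27, 0.027). It was also called with background subtraction (-0.15) and recovered reads (-0.26), both chosen after seeing the data (adjusted p = 0.022 each). It was at 0.00 without wild-type replicate 2 and 0.09 without mutant replicate 1, with adjusted p from 0.0024 to 0.86 over the alternatives. Insect toxins was called without wild-type replicate 1 (0.60, adjusted p = 0.038) or mutant replicate 2 (0.70, 0.039) and with recovered reads (0.60, 0.028). It was at 0.13 without wild-type replicate 2, 0.11 without mutant replicate 1 and 0.05 with quantile normalization, with adjusted p from 0.028 to 0.86 over the alternatives. Heat shock was called without wild-type replicate 2 (0.38, adjusted p = 0.014) or mutant replicate 1 (0.22, 0.043). It was at -0.11 without wild-type replicate 1 and 0.01 without mutant replicate 2, with adjusted p from 0.014 to 0.94 over the alternatives. Exopolysaccharides was called lower among genes with a mean RPKM of at least 10 (-0.36, camera adjusted p = 0.003). It was called in opposite directions without mutant replicate 1 (-0.22) and without mutant replicate 2 (0.36), with adjusted p from 0.003 to 0.97 over the alternatives. In these 11 lists, 1 gene passed when adjusted over its list alone: Pchl3084_2864, an enoyl-CoA hydratase family gene of the fatty acid list, with 67.0 ± 2.75 RPKM in the wild type and 32.5 ± 1.47 in the mutant (limma adjusted p = 0.047, and 0.24 over all genes).

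At least 2-fold differences in all 4 pairs were found for 16 lower and 22 higher genes, chosen after their values were seen. The lower set held mmsA (233 ± 0.11 against 92.05 ± 13.0 RPKM), which encodes methylmalonate-semialdehyde dehydrogenase, and the amine oxidase gene Pchl3084_2277 (125 ± 21.0 against 45.2 ± 13.0 RPKM, SD, n = 2), beside phz, hut, aprA, sodB and prpC genes. Of the 22 higher genes, 20 had a wild-type mean under 5 RPKM, in the range where mutant replicate 1 had few values. The 2 others were Pchl3084_4408 (17.3 ± 2.78 against 53.2 ± 20.5 RPKM) and Pchl3084_2644 (9.72 ± 0.11 against 20.5 ± 0.35 RPKM, SD, n = 2), both of unknown function. Mutant replicate 2 must also be at least 2-fold higher under this rule. The raised low values of mutant replicate 1 make the rule easier to meet but cannot meet it alone.

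With no gene past the threshold, there were 0 runs of at least 3 neighbouring called genes. Genes at least 2-fold different in all 4 pairs formed 2 such runs, both lower and both in the histidine cluster (hutU to hisX and hisV to the hutH gene Pchl3084_0407), where 1000 random orders gave at most 0. Bacterial genes are transcribed as operons, which random orders of single genes ignore. An excess of runs over random orders therefore describes which neighbours moved together and does not show an effect of the strain. Runs of called genes numbered 4 to 10 without wild-type replicate 1, wild-type replicate 2 or mutant replicate 1, where random orders gave at most 1. Without mutant replicate 2 there were 141, where random orders gave 28.0 on average and at most 48.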

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

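Background subtraction, rescaling without 3 abundant RNAs and voom on recovered reads were chosen after seeing the data. The count of genes past the threshold stayed at 0 in limma with other pseudocounts, filters and scalings, without the trend and with these 3 added settings. There the lowest adjusted p was 0.065 to 0.64, and 382 to 824 genes had an unadjusted p under 0.05. The count was 16 with the robust variance model, 6 at an adjusted p under 0.1, and 35 to 1271 when 1 library was left out. The replicate numbers share no stated day or batch, and the differences between replicates 1 and 2 correlated at 0.36 across genes between the strains. With the replicate block 211 genes were called, 8 of 10 phenazine genes passed with a median of -1.89, there were 10 runs of neighbouring genes, and 10 lists were called. The block leaves fewer residual degrees of freedom than the 2 of the main fit. Its gene calls thus lean on the variance shared across genes, and passing the threshold in it is not read as support. The block ended the calls of rRNA and tRNA genes (adjusted p = 0.095) and terminal oxidases (0.062). It called phzI (limma adjusted p = 0.027), phzR (0.0032) and all 10 genes of the histidine cluster, and called Pchl3084_1490 to Pchl3084_1492 higher. The phenazine median was -2.42 to -1.39 when 1 library was left out. Runs numbered 4 to 141 when 1 library was left out, 2 with the robust variance model and 2 among genes at least 2-fold different in all 4 pairs. The cause of these changes was not tested, and leaving out a library also leaves fewer samples.

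The 12 called lists became 0 with an estimated correlation, 0 with fry and 7 to 13 when 1 library was left out. The estimated correlation and fry rest on 2 residual degrees of freedom, so the 0 of each does not count against the lists. camera does not use the trend or the robust choice, so those settings move nothing there. Over all alternatives, 159 values of called lists stayed called in the same direction, 55 were no longer called and 2 reversed. Of lists not called, 200 values stayed so in the same direction, 14 became called in the same direction and 19 reversed. Values that reversed were counted as such even where called, as for exopolysaccharides without mutant replicate 1 (-0.22) and with a mean RPKM of at least 10 (-0.36). When 1 library was left out, relative medians ran from -0.12 to 0.80 for phage and bacteriocins, -0.44 to 0.01 for rRNA and tRNA genes, -0.27 to 0.09 for flagella, -0.11 to 0.38 for heat shock, -0.21 to 0.14 for shikimate, -0.22 to 0.19 for DNA repair, -0.22 to 0.36 for exopolysaccharides, -0.04 to 0.11 for secreted hydrolases and -0.17 to 0.10 for fatty acids. With a mean RPKM of at least 10 they were -0.04 for shikimate, -0.36 for exopolysaccharides and -0.13 for fatty acids. With quantile normalization they were -0.12 for exopolysaccharides and 0.00 for secreted hydrolases and fatty acids. Shikimate was -0.04 with no filter and -0.03 on recovered reads, and exopolysaccharides -0.25 after background subtraction.

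Of values of named genes, 677 kept their direction and side of the threshold, 175 passed it in the same direction and 5 reversed. Pchl3084_2139 was -0.33 with quantile normalization, -0.39 after background subtraction and -0.12 to 0.69 when 1 library was left out. Pchl3084_4663 was 0.04 without 3 abundant RNAs and -0.18 to 0.00 when 1 library was left out. The cause was not tested. The median gene had at least 391 reads in each library, and genes under 5 RPKM are limited by the raised low values of mutant replicate 1.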

Other observations

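Tests on the low values of mutant replicate 1, on depth, on the strain, on siderophore genes and the first 2 on phage genes were chosen after the values were seen, and so were the genes named here. The origin test and the recA, lexA and recN test were not.

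Neighbouring low-level genes for indole and aromatic compounds formed no list of their own. Without mutant replicate 1, iaaH and Pchl3084_1488 to Pchl3084_1492 passed the threshold, higher in the mutant, without mutant replicate 2 Pchl3084_1483 to Pchl3084_1491 did so, and without wild-type replicate 1 or 2 only Pchl3084_1491 or only Pchl3084_1492 did. iaaH, which encodes indoleacetamide hydrolase, had 2.49 and 1.64 RPKM in the wild type and 7.52 and 6.03 in the mutant (log2 fold change 1.35, limma adjusted p = 0.46, 0.63 with quantile normalization and 1.50 with background subtraction), and the dioxygenase subunit gene Pchl3084_1489 had a log2 fold change of 1.22 (limma adjusted p = 0.44, higher in 4 of 4 pairs), 0.55 with quantile normalization and 1.15 with background subtraction. The 1st percentile of mutant replicate 1 was 6.12 RPKM, in the range of these values. Pchl3084_1492, a transporter gene at the end of that stretch, had 8.47 and 9.08 RPKM in the wild type, 11.50 in mutant replicate 1 and 43.7 in mutant replicate 2. Elsewhere, the nearby genes for a putative RstA regulator (Pchl3084_2457) and a putative lipoprotein (Pchl3084_2460) had log2 fold changes of 1.22 and 1.58 and were higher in 4 of 4 pairs.

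Cytochrome oxidase genes differed in their pattern. The ctaD gene Pchl3084_0326 had 49.6 RPKM in wild-type replicate 1 against 134 in wild-type replicate 2, and 171 and 145 in the mutant. The cbb3-type ccoN gene Pchl3084_1908 had 162 and 163 RPKM in the wild type, 59.0 in mutant replicate 1 and 143 in mutant replicate 2. The efflux gene Pchl3084_3346 was likewise at 16.8 RPKM in mutant replicate 1 and at 61.0 to 78.05 in the other 3 libraries. argO had 47.3 and 274 RPKM in the wild type and 14.3 and 24.3 in the mutant.

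Mutant replicate 1 lacked low values that the other 3 libraries had. The strain as the cause is argued against by mutant replicate 2, whose 1st percentile was 1.04 times that of the higher wild-type library. Lower depth is argued against by thinning mutant replicate 2 to the depth of replicate 1. Over the 4671 genes with recovered reads, the thinned replicate 2 had a 1st percentile of 2.26 RPKM against 6.34 in replicate 1. An even background, as from genomic DNA, may account for the excess: its median was 4.49 RPKM for genes at 1 to 3 RPKM in the wild type and 2.79 for genes at 5 to 8, a ratio of 0.62 (95% bootstrap interval 0.55 to 0.68), where an excess in proportion to expression would be larger for the second group. The ratio under 1 is not explained by a constant alone, and the protocol included DNase. Distance from dnaA gave a Spearman rho of 0.04 across 852 genes (permutation p = 0.25), which leaves a gradient from the replication origin undecided.

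The same background is a candidate explanation for the rise of siderophore and iron uptake genes. After subtraction of each library's 1st percentile the relative median of the list went from 0.46 to 0.33, a share of 0.73, and the list was still called (camera adjusted p = 9.3e-07), between the bounds set for and against it. What part of the rise it accounts for therefore cannot be told apart from a change in the mutant, because subtraction of a constant is only a rough correction of genes this close to the background. Without mutant replicate 1 the relative median was 0.21, with the list's median gene at 5.88 RPKM in mutant replicate 2 against 4.32 and 4.16 in the wild type. That remainder does not come from mutant replicate 1, but it rests on 1 mutant library.

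Of the phage list, 18 genes between Pchl3084_1194 and Pchl3084_1231, which encode a phage tail or R-type pyocin, had a median of 56.0 RPKM in mutant replicate 1 and of 23.05, 29.9 and 23.05 in wild-type replicates 1 and 2 and mutant replicate 2. The even background is argued against by their excess over mutant replicate 2, 8.02 times that of genes under 5 RPKM, and the strain by mutant replicate 2, at 0.87 times the wild-type mean. An SOS response in that culture is argued against by recA, lexA and recN, which were lower there than in mutant replicate 2 by a median log2 difference of -0.82 after background subtraction, and without it recA had 145 RPKM in mutant replicate 1 and 247 in mutant replicate 2. High values in mutant replicate 2 may make this difference. The median gene of the DNA repair and SOS list had 33.24 RPKM in mutant replicate 2, 22.93 in mutant replicate 1, and 24.16 and 24.35 in the wild type. That list thus showed no rise over the wild type in mutant replicate 1. Activation of the cluster in that 1 culture by another route, or extra copies of its DNA, may be open explanations, and neither was tested.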
